A study of Mus musculus with 12 samples.

How the data were processed

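Spleen RNA was measured on Illumina mouse expression arrays in 12 samples that fall into 4 groups of 3. The groups cross the genotype (C57Bl/6 wild type, WT, or mice carrying a human MUC1 transgene, Tg) with the time after immunization (24 h or 72 h). Per the labels' protocols, every mouse received an intravenous injection of 1000000 dendritic cells grown from bone marrow. The cells had been loaded overnight with a synthetic peptide of 100 residues from human MUC1 at 30 µg/mL and matured with poly-ICLC, a stabilised double-stranded RNA mimic, at 30 µg/mL. Per the labels' protocols, RNA was extracted with Trizol, cleaned on RNeasy columns with DNase treatment, checked on a Bioanalyzer, and turned into biotinylated cRNA with the Ambion MessageAmp kit. No unimmunized spleen was analysed here. The design text states that splenic RNA of the vaccination groups (n = 3) was pooled, while the labels call the 3 arrays of a group replicates. Whether 1 array holds 1 mouse or 1 aliquot of a pool is not given in the sources used here. The replicates are therefore arrays that may be technical, and every p-value measures only the spread between these arrays.

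The main table holds the probe intensity deposited by the authors for 45281 probes on each array, on a linear scale and not normalized. Beside each intensity the authors deposited a detection p-value per probe and array, per the file headers. The scanner software and its settings are not given in the sources used here. All columns of the table matched 1 sample each, so 0 columns of sample values were left unmapped. A second deposited table, the authors' processed values of the same arrays, holds scores between 0.182 and 2.147. How the authors made these scores is not given in the sources used here. Of its 45281 probes, 13782 were empty on every array, 14 were empty on the arrays of 1 time only, and 31485 were complete. The median score per array was 0.2208, 0.2233 and 0.2228 for WT at 24 h, 0.224, 0.2218 and 0.2281 for Tg at 24 h, 0.2326, 0.233 and 0.2296 for WT at 72 h, and 0.2277, 0.2251 and 0.2261 for Tg at 72 h.

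The scores could not be tied to the intensities by probe name. The rank correlation between an array's scores and its own intensities lay between -0.0235 and -0.00922. Between arrays of the same time the scores correlated at 0.9167 to 0.9392, but between arrays of different times at 0.3945 to 0.4095. The intensities correlated at 0.9044 to 0.9315 within a time and at 0.9036 to 0.9298 between times. Scale, centring and the naming of the scores by probe all stay unknown. They were used without gene names, on the log2 scale, and only to count calls between the genotypes within 1 time.

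The intensities were processed in R 4.3.3 with limma 3.58.1. The neqc function corrected the background by normexp convolution with negative controls inferred from the detection p-values, added an offset of 16, applied quantile normalization between arrays and took log2. The offset shrinks the fold changes of dim genes, so the differences given here understate those. Probes were tested when their detection p was under 0.01 on at least 3 of the 12 arrays, which kept 18482 probes. Over the 12 arrays, 15491 probes were detected on all arrays and 25081 on none. Arrays give no read depth. Their number, 3 per group, limits the precision.

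Gene names came from the annotation table of the array platform, which can be old. Of the 45281 probes, 34885 carried 1 gene symbol, 18 carried several and 10378 none. Symbols were checked through the Entrez identifier against a RefSeq gene table of assembly GRCm38.p6, where 34807 probes matched and 0 symbols changed. Probes with several symbols were not named, and 2833 tested probes had no name. A gene was represented by its tested probe with the highest mean intensity over all arrays, which gave 10060 tested genes. Of these, 3839 had more than 1 tested probe. Coordinates were not used here.

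One limma model with the 4 group means was fitted to all 12 arrays, with 1 shared estimate of the spread. It gave 5 comparisons, namely Tg minus WT at 24 h and at 72 h, 72 h minus 24 h in WT and in Tg, and the change of the Tg minus WT difference from 24 h to 72 h (the interaction). P-values were adjusted by the Benjamini-Hochberg method over the tested probes, and genes at an adjusted p under 0.05 were called. All adjusted p-values of genes are limma's. A gene whose probes were not detected on any array of the dimmer group has only a bound there, given as "at least N-fold". The bound sets the bright group's mean normalized level against the dim group's mean of, per array, the higher of the lowest level among detected probes and the dim probe's own level. Counts of changes of at least 2-fold use fitted differences, also for such genes, whose bound can be smaller.

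The 32 gene lists used here were pancreatic acinar, pancreatic endocrine, pancreatic duct and epithelium, adipocyte, smooth muscle and stroma, skeletal muscle, interferon-stimulated, T cell, cytotoxic and NK, regulatory T cell and tolerance, T follicular helper and activation, B cell, plasma cell and immunoglobulin, germinal centre, conventional, mature and plasmacytoid dendritic cell, macrophage and red pulp, monocyte, neutrophil, eosinophil with basophil and mast cell, erythroid, megakaryocyte and platelet, proliferation, ER stress and secretion, immediate early and heat shock, chemokine and cytokine, circadian clock, sex-linked, ribosomal protein, oxidative phosphorylation, and housekeeping genes. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists of a comparison. Camera compares a list with all other tested genes, while fry tests whether its members move, on balance, one way. A list was called when its camera adjusted p at the preset correlation was under 0.05. Fry's directional test passed for 48 further list results that camera did not call. Some tested members stand in 2 lists. The plasmacytoid dendritic cell list shares Klk1 with the acinar list, Bst2 with the interferon list and Spib with the B cell list, and the chemokine list shares Cxcl10 with the interferon list. The chemokine list also shares Ccl5 and Ifng with the cytotoxic list and Ccl19 with the mature dendritic cell list. The erythroid and housekeeping lists share Tfrc. The T cell and mature dendritic cell lists share Ccr7, and the follicular helper and germinal centre lists share Bcl6.

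The groups, the model, the lists, the processing alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 largest rises and the 10 largest falls among called genes whose arrays do not overlap between the groups, 5 each way for the interaction, up to 6 members of each list by p in each comparison, all tested acinar genes, and Muc1. The alternatives were no background correction, median scaling in place of quantile normalization, an offset of 50, no filter on dim probes, detection on all 12 arrays, a fit of only the groups compared, array weights, eBayes with trend and robust, a fold threshold of 2, the mean of a gene's probes, the replicate number as a block, the authors' scores, and leaving out each array in turn. Counting all tested probes in place of genes was added after seeing the data.

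The model was tested on simulated data for the 24 h genotype comparison over 18482 probes. It recovered 32% of 50 probes changed 1.25-fold, 74% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and 16 of its 168 calls (9.52%) were false. The list test, run over 31 lists, called the 1 list that had been shifted and 0 others. The simulated noise was drawn independently for each probe, so this result does not cover lists whose members vary together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.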

Results

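The study asked how the spleens of wild-type mice and of mice carrying human MUC1 as a transgene differ after the same dendritic cell vaccine, in which the MUC1 peptide is foreign to the former and a self-antigen to the latter. Gene expression in whole spleen was measured 24 h and 72 h after the injection, in 4 groups of 3 arrays. Per array, 16868 to 17881 of 45281 probes were detected (37.25% to 39.49%), and the median probe intensity lay between 61.3 and 76.7 in the scanner's arbitrary units. Arrays of the same group correlated at 0.99512 to 0.9968 and arrays of different groups at 0.97381 to 0.98968 (normalized log2 values across probes, which are not independent replicates). No pair of arrays held identical values. The median SD of a probe within a group was 0.09191 on the log2 scale for WT at 24 h and 0.08983 for Tg at 24 h. Below, Tg against WT means Tg minus WT, and intensities are means ± SD over 3 arrays before normalization.

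The gene behind the transgene was examined first. Mouse Muc1, which encodes a membrane-bound epithelial mucin, gave an intensity of 87.3 ± 11.2 in Tg and 75.73 ± 9.26 in WT at 24 h, at least 1.04-fold higher in Tg, which did not pass (adjusted p = 0.0984), and was detected on 2 of the Tg arrays and 0 of the WT arrays. At 72 h it was near the detection limit in both genotypes and did not pass either (adjusted p = 0.634). The probe was designed for the mouse gene, and whether it binds the human transcript was not tested, so it does not check the genotype labels.

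At 24 h the largest differences between the genotypes lay in digestive enzymes of the exocrine pancreas, which Tg spleens held at far lower levels than WT spleens. Amy2a5, pancreatic alpha-amylase, had an intensity of 9494 ± 235 in WT and 106.8 ± 18.2 in Tg, a 151-fold fall (log2 difference -7.24, SE 0.0812, adjusted p = 5.81e-14). Its 3 probes differed in size, at -7.24, -5.22 and -1.49. The last 2 were undetected in Tg at 24 h, so their values are fitted values without a measured size. Of the 30 tested acinar genes, 27 fell, 1 rose and 2 did not pass, and the counts of rises and falls adjusted over the list alone were 1 and 27. Pla2g1b, Pnliprp2, Cuzd1 and Prss2 were undetected in both genotypes at 24 h. They stand at their fitted values in these counts and in the list mean and medians below. The elastase Cela2a fell at least 28.8-fold (adjusted p = 3.17e-14), colipase (Clps) at least 9.98-fold, carboxypeptidase B (Cpb1) at least 8.67-fold and pancreatic ribonuclease (Rnase1) at least 7.77-fold. The trypsin genes Try5 (at least 15.3-fold), Try4 (14.4) and Try10 (9.28) also fell, but near-identical paralogs can share probes, so the split among them is uncertain. Detected in both genotypes, Ctrl (-1.73), Cela1 (-1.24) and the zymogen granule protein gene Gp2 (-1.01) fell on the log2 scale. The member that rose was Erp27 (0.26, adjusted p = 0.00445), a chaperone of the endoplasmic reticulum. The list mean was -2.45 and its median -2.26, or -1.57 with 18 genes set to their bounds (camera adjusted p = 4.80e-39, and 3.04e-05 with an estimated correlation). The study is known to report these enzymes in these spleens, so the list is not independent evidence of their direction.

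Red cell precursor genes and cell division genes fell with them. Of 24 tested erythroid genes, 20 fell, 0 rose and 4 did not pass (1 rise and 22 falls adjusted over the list alone), with a list mean of -1.32 (camera adjusted p = 1.80e-30). The largest were Hemgn, a nuclear factor of blood progenitors (277.2 ± 45.3 in Tg against 1130 ± 55.3 in WT, log2 -2.22, SE 0.0626, adjusted p = 2.80e-10), and Kel, the Kell blood group protein (-1.99). Ank1, the ankyrin of the red cell skeleton (-1.90), Mgst3 (-1.76), Ermap (-1.71) and the transcription factor Tal1 (-1.70) fell as well. Tfrc, the transferrin receptor that is also on the housekeeping list, fell by 1.46. Of 26 proliferation genes 25 fell and 1 did not pass (26 falls adjusted over the list alone), with a list mean of -0.78 (camera adjusted p = 1.53e-27). They included the replication licensing factor Cdc6 (-1.38), survivin (Birc5, -1.22), the mitotic kinase Cdk1 (-1.06), the centromere histone Cenpa (-0.83) and topoisomerase Top2a (-0.83). With an estimated correlation the adjusted p was 3.04e-05 for the erythroid list and 7.01e-05 for the proliferation list.

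Macrophage genes were lower and B cell genes higher in Tg spleens at 24 h. Of 17 genes of macrophages and the red pulp, the blood-filtering part of the spleen, 11 fell and 6 did not pass (11 falls adjusted over the list alone, mean -0.27, camera adjusted p = 1.64e-05, and 0.00712 with an estimated correlation). Examples were the heme-degrading enzyme Hmox1 (-0.37), complement C1qb (-0.36), the surface marker Adgre1, or F4/80 (-0.38), and Spic, a transcription factor of red pulp macrophages (-0.33). Of 11 B cell genes 7 rose and 4 did not pass (10 rises adjusted over the list alone, mean 0.30, camera adjusted p = 3.66e-05, and 0.0326 with an estimated correlation). Ms4a1, or CD20, rose by 0.45 (adjusted p = 6.43e-05), the B lineage factor Ebf1 by 0.44, Fcrla by 0.32 and Fcer2a, or CD23, by 0.27. Of 17 neutrophil genes 5 fell and 12 did not pass (7 falls adjusted over the list alone, mean -0.15, camera adjusted p = 0.0229), a call not held with an estimated correlation (adjusted p = 0.0799 with an estimated correlation). Single genes rose outside these lists. Pisd-ps3 rose by 1.43 (adjusted p = 3.88e-08), although its other probe gave 0.07, 2900060B14Rik by 1.12 (adjusted p = 2.68e-07), and Clec2d, a ligand of the NK cell receptor family, by 1.09 (7411 ± 773 against 3519 ± 221). Akap13, a scaffold of protein kinase A, rose by 0.96, while its other probe gave 0.26 (adjusted p = 0.19). Taf15 (0.81), Fkbp15 (0.74), Gng2 (0.71), Scrn2 (0.71) and the DNA repair enzyme Smug1 (0.70) followed.

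The lists of T cell genes (3 of 12 rose, mean 0.15, camera adjusted p = 0.0591) and interferon-stimulated genes (4 of 28 rose, 1 fell, mean 0.10, camera adjusted p = 0.152) were not called at 24 h. Neither were those of regulatory T cell (0.16), cytotoxic and NK (0.09), mature dendritic cell (0.10), follicular helper (0.08), germinal centre (0.13), plasmacytoid dendritic cell (0.11), circadian clock (0.08), ribosomal (0.03), immediate early (0.02), plasma cell (0.03), monocyte (-0.04), smooth muscle (-0.07), megakaryocyte (-0.03), oxidative phosphorylation (-0.03), eosinophil (-0.09), duct (-0.23) and sex-linked genes (0.12), given as list means. Fry's directional test did pass for the T cell and interferon lists (fry adjusted p = 0.00114 and 0.000131). Among others, it also passed for the regulatory T cell (0.0049), cytotoxic (0.000725) and plasmacytoid (0.000222) lists, but not for the monocyte list (0.498). For 6 uncalled lists the mean, the median and the direction of the test did not share 1 sign. These were the adipocyte (mean -0.28, median 0.06), skeletal muscle (-0.08 and 0.05), conventional dendritic cell (0.03 and -0.00), ER stress (0.00 and -0.02), housekeeping (-0.07 and 0.07) and chemokine (0.01 and 0.01, test direction down) lists. Among tissue markers beside the acinar genes, the adipocyte genes Car3 (-1.06) and Adipoq (-0.77) and the muscle gene Mylpf (-0.64) fell. Of the 20 endocrine pancreas genes fixed, 17 were on the array and 0 were detected on any array, so that list was not tested.

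In all, 1182 genes rose and 1066 fell in Tg at 24 h among 10060 tested genes, of which 3 rose and 166 fell at least 2-fold. Of those 166 falls, 22 were acinar, 17 erythroid and 6 proliferation genes. These counts use fitted values, and the acinar gene Dmbt1 and the proliferation gene Tpx2, undetected in Tg, had bounds of only 1.35-fold and 1.63-fold.

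**Figure D1:**
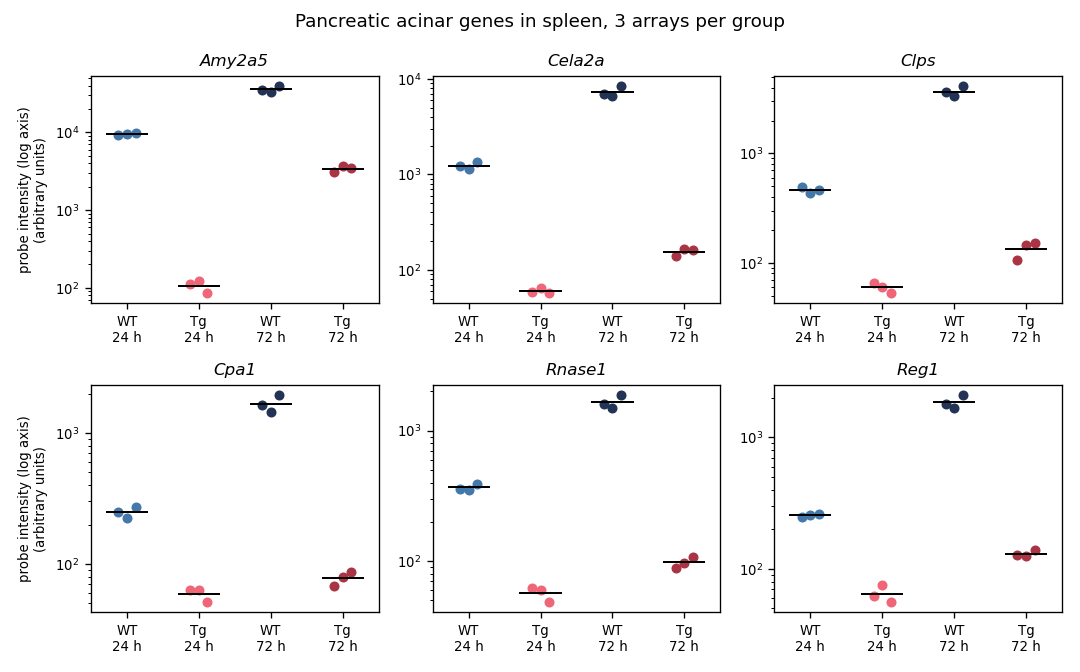
Probe intensity in arbitrary units, on a log axis, of 6 pancreatic acinar genes in the 4 groups, with 1 point per array and the group mean as a black line. Amy2a5 averaged 9494 in WT and 106.8 in Tg at 24 h, and 35790 and 3397 at 72 h.

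At 72 h the acinar genes were again lower in Tg. Of 30 acinar genes 29 fell, 0 rose and 1, the secretory transcription factor Bhlha15, did not pass (29 falls adjusted over the list alone). The list mean was -3.83 and the median -4.27, or -4.16 with 11 genes set to their bounds (camera adjusted p = 1.79e-60, and 1.10e-05 with an estimated correlation). As at 24 h, the list is not independent evidence. Cela2a had an intensity of 155.8 ± 13.5 in Tg and 7264 ± 950 in WT, a 71.9-fold fall (log2 -6.17, SE 0.0569, adjusted p = 1.19e-14). On the log2 scale Clps (-5.51), Try4 (-5.47), Cpb1 (-5.10), Rnase1 (-5.03), the zymogen granule lectin Zg16 (-4.60), Reg1 (-4.55) and Amy2a5 (-3.44) fell. Undetected in Tg at 72 h, the elastase Cela3b fell at least 31.7-fold, Try10 at least 30.6-fold, the lipase Cel at least 20.1-fold, chymotrypsinogen (Ctrb1) at least 19.6-fold and phospholipase Pla2g1b at least 10.8-fold. The trefoil factor Tff2, on the duct list, fell at least 12.5-fold.

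Erythroid and proliferation genes were again lower in Tg. Of 24 erythroid genes 20 fell and 4 did not pass (21 falls adjusted over the list alone, mean -0.94, camera adjusted p = 3.42e-26, and 3.85e-05 with an estimated correlation). Examples were the red cell spectrin Sptb (-1.36, SE 0.0671, adjusted p = 6.25e-08), Kel (-1.35), Tal1 (-1.34) and Klf1, the master regulator of globin genes (-1.26). Of 26 proliferation genes 24 fell and 2 did not pass (24 falls adjusted over the list alone, mean -0.61, camera adjusted p = 8.34e-23, and 0.000145 with an estimated correlation), among them Birc5 (-1.04) and ribonucleotide reductase Rrm2 (-1.01).

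B cell genes were again higher in Tg at 72 h. Of 11 B cell genes 10 rose and 1 did not pass (11 rises adjusted over the list alone, mean 0.29, camera adjusted p = 1.61e-05, and 0.0316 with an estimated correlation). They included Blnk, an adaptor of the B cell receptor (0.39), Fcrla (0.39, adjusted p = 0.000291), Fcer2a (0.32) and Ms4a1 (0.25). Of 12 T cell genes 5 rose and 7 did not pass (6 rises adjusted over the list alone, mean 0.21, camera adjusted p = 0.0039, and adjusted p = 0.097 with an estimated correlation), led by the T lineage factor Bcl11b (0.43) and Cd3g of the T cell receptor complex (0.34). Smaller calls, each lost with an estimated correlation, were those of 24 chemokine and cytokine genes (5 rose, also 5 adjusted over the list alone, mean 0.11, camera adjusted p = 0.0398, adjusted p = 0.115 with an estimated correlation) and of 10 mature dendritic cell genes (4 rose, 5 adjusted over the list alone, mean 0.19, camera adjusted p = 0.0398, adjusted p = 0.115 with an estimated correlation). The call of 8 follicular helper and activation genes was of the same kind (5 rose, also 5 adjusted over the list alone, mean 0.14, camera adjusted p = 0.0495, adjusted p = 0.127 with an estimated correlation). Ccl19, a chemokine that draws T cells and mature dendritic cells and is on the chemokine and mature dendritic cell lists, rose by 0.42, lymphotoxin beta (Ltb) by 0.35 and the maturation marker Cd83 by 0.27. The follicular helper call ended without any 1 of 8 arrays, the exceptions being Tg 24 h replicate 3, WT 72 h replicates 1 and 2 and Tg 72 h replicate 2 (adjusted p 0.0524 to 0.0709). The mature dendritic cell call ended without WT 72 h replicate 3 or Tg 72 h replicate 1 or 3 (0.0593 to 0.0634), and the chemokine call without WT 72 h replicate 2 or Tg 72 h replicate 1 (0.0551 to 0.0635).

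Single genes also rose at 72 h. Dct, a melanin synthesis enzyme, was undetected in WT and rose at least 3.29-fold in Tg (177.5 ± 11.1 against 59.43 ± 9.34, adjusted p = 1.02e-09), and its other probe rose as well (adjusted p = 5.39e-08). The others were smaller, with 0.93 for 1110017D15Rik (adjusted p = 0.00462), at least 1.44-fold for Speer1, 0.67 for Speer3, 0.66 for Edem1, which helps clear misfolded proteins, at least 1.19-fold for Stfa1, and 0.65 for the oxygen sensor Egln1, whose other probes gave 0.28 and 0.30. The antiviral genes Isg15 (-0.88) and Rsad2 (-0.80) fell, while 20 of 28 interferon-stimulated genes did not pass, 3 rose and 5 fell (list mean -0.07, camera adjusted p = 0.589). The macrophage list was not called at 72 h (2 of 17 fell, mean -0.08), nor was the duct list (2 of 7 fell, mean -0.66), the conventional dendritic cell list (5 of 13 rose, mean 0.18, camera adjusted p = 0.0547) or the adipocyte list (2 of 5 fell, mean -0.06, median 0.08). The means of the ribosomal list (0.04, median -0.01) and of the megakaryocyte list (0.03, test direction down), neither called, did not share their sign with the median or the test. Fry's directional test passed for the macrophage, duct and conventional dendritic cell lists (fry adjusted p = 0.00168, 2.55e-05 and 0.00168). It also passed for the interferon list (0.00305), but not for the adipocyte list (0.169).

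At 72 h 1004 genes rose and 1118 fell, of which 1 rose and 114 fell at least 2-fold, 27 of the falls being acinar, 16 erythroid and 2 proliferation genes. With median scaling in place of quantile normalization the split was 676 up and 1253 down. The genotype comparisons at 24 h and 72 h share no array, but 1 fit gave both, with the same estimate of each probe's spread. Their calls are thus not independent, and numbers for independent calls are only a reference. The comparisons had 696 falls (118.5 for independent calls) and 283 rises (118) in common, while 61 genes were called in opposite directions (237.7). Across genes, which are not independent replicates, the log2 differences at both times correlated at r = 0.709 and rho = 0.3803.

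**Figure D2:**
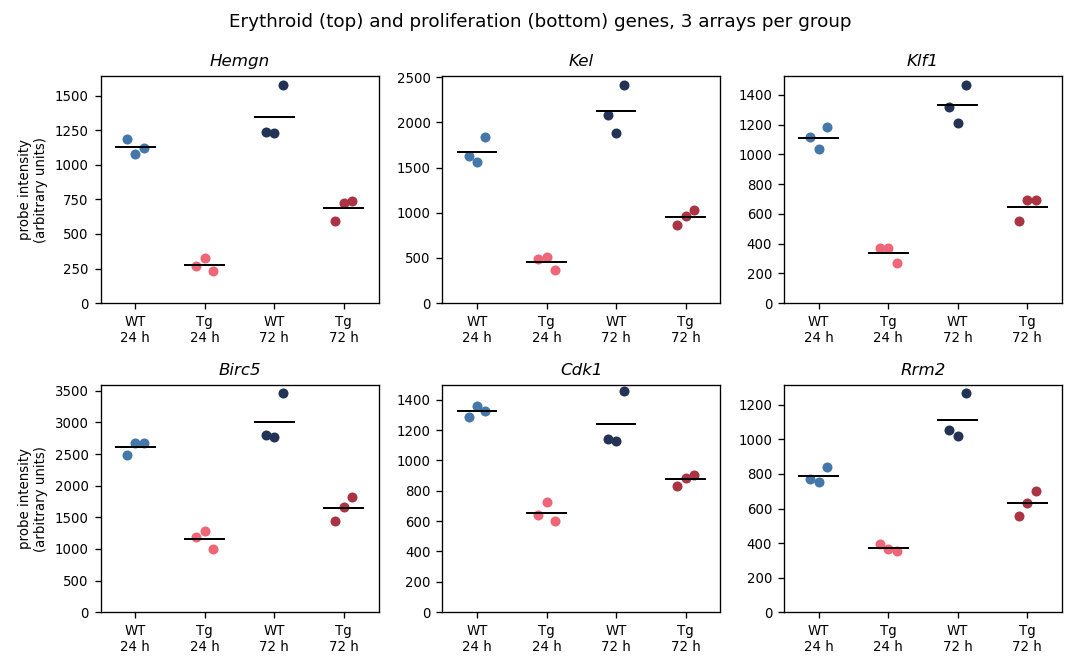
Probe intensity in arbitrary units of the erythroid genes Hemgn, Kel and Klf1 (top) and the proliferation genes Birc5, Cdk1 and Rrm2 (bottom), with 1 point per array and the group mean as a black line. Hemgn averaged 277.2 in Tg and 1130 in WT at 24 h, and 684.8 and 1348 at 72 h.

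From 24 h to 72 h, interferon-stimulated genes fell in WT spleens while pancreatic acinar genes rose. All 28 tested interferon genes fell (28 adjusted over the list alone, mean -1.46, camera adjusted p = 2.48e-31, and 2.81e-05 with an estimated correlation). Ifit3, which binds viral RNA complexes, went from 10990 ± 589 to 1043 ± 124 (log2 -3.23, SE 0.0593, adjusted p = 1.83e-11). The dynamin-like antiviral GTPases Mx2 (-2.62) and Mx1 (-2.60), the oligoadenylate synthetase Oas2 (-2.50), the ISG15 protease Usp18 (-2.41), the interferon regulator Irf7 (-2.41), Oasl1 (-2.21) and Ifit2 (-2.20) followed. Of 30 acinar genes 28 rose and 2 did not pass (28 adjusted over the list alone, mean 2.29, median 2.57, or 2.48 with 4 genes at their bounds, camera adjusted p = 3.38e-38, and 3.31e-05 with an estimated correlation). Clps rose by 3.35, Reg1 by 3.34, Zg16 by 3.25, Cpa1 by 3.23, Cela2a by 2.81 and Amy2a5 by 2.07, and Pla2g1b rose at least 10.7-fold and Pnliprp2 at least 6.79-fold. Here too the study's own reports make the acinar list no independent evidence.

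Inflammatory and phagocyte genes fell over the same time in WT. Of 24 chemokine and cytokine genes 18 fell and 1 rose (18 and 1 adjusted over the list alone, mean -0.56, camera adjusted p = 3.00e-10), including the T cell attractants Cxcl10 (-2.16, also on the interferon list) and Cxcl9 (-1.46) and the cytokines Il15 (-0.84) and Il1b (-0.74). The monocyte attractant Ccl12 fell at least 2.27-fold. Of 17 macrophage genes 10 fell (11 adjusted over the list alone, mean -0.42, camera adjusted p = 8.42e-06), such as C1qb (-0.96) and Spic (-0.75), and of 10 mature dendritic cell genes 6 fell (7 adjusted over the list alone, mean -0.34, camera adjusted p = 0.000155), such as Fscn1 (-0.48). Of 8 follicular helper and activation genes 4 fell (5 adjusted over the list alone, mean -0.23, camera adjusted p = 0.00653), among them the early activation marker Cd69 (-0.53). With an estimated correlation these 4 lists had adjusted p = 0.00108, 0.00506, 0.0131 and 0.0454, in that order. Of 12 monocyte genes 6 fell and 2 rose (7 and 2 adjusted over the list alone, mean -0.37, camera adjusted p = 0.00663, adjusted p = 0.0726 with an estimated correlation), led by Ly6c1 (-1.36). The conventional dendritic cell list (3 of 13 fell, also 3 adjusted over the list alone, mean -0.17, camera adjusted p = 0.0277, adjusted p = 0.182 with an estimated correlation) lost its call with median scaling (adjusted p = 0.0585, against 0.00317 to 0.0585 over all alternatives).

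Erythroid and proliferation genes rose in WT. Of 24 erythroid genes 18 rose (19 adjusted over the list alone, mean 0.38, camera adjusted p = 2.87e-09, and 0.00108 with an estimated correlation), such as Sptb (0.90) and the heme synthesis enzyme Alas2 (0.55). Of 26 proliferation genes 16 rose (also 16 adjusted over the list alone, mean 0.24, camera adjusted p = 3.98e-05, and 0.0143 with an estimated correlation), such as Cdc20 (0.76) and Rrm2 (0.74). Of 17 neutrophil genes 8 rose and 2 fell (9 and 2 adjusted over the list alone, mean 0.18, camera adjusted p = 0.0277, adjusted p = 0.0741 with an estimated correlation), including myeloperoxidase (Mpo, 0.62). Of 10 megakaryocyte genes 4 rose (5 adjusted over the list alone, mean 0.18, camera adjusted p = 0.0342, adjusted p = 0.091 with an estimated correlation), a call that ended without WT 24 h replicate 1 or 3 (0.0543 to 0.0577). Dct fell at least 3.34-fold. The B cell (mean 0.01, median -0.03), circadian clock (-0.06 and 0.01), plasmacytoid dendritic cell (-0.05 and 0.05), smooth muscle (0.02 and -0.10) and germinal centre (0.05 and -0.08) lists were not called and had means and medians of opposite sign.

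In WT 1729 genes rose and 1427 fell from 24 h to 72 h, of which 43 rose and 72 fell at least 2-fold. Of these, 26 rises were acinar genes and 18 falls interferon genes. The chip and hybridization day of each array are not given in the sources used here, so a batch that follows time or genotype could not be tested.

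**Figure D3:**
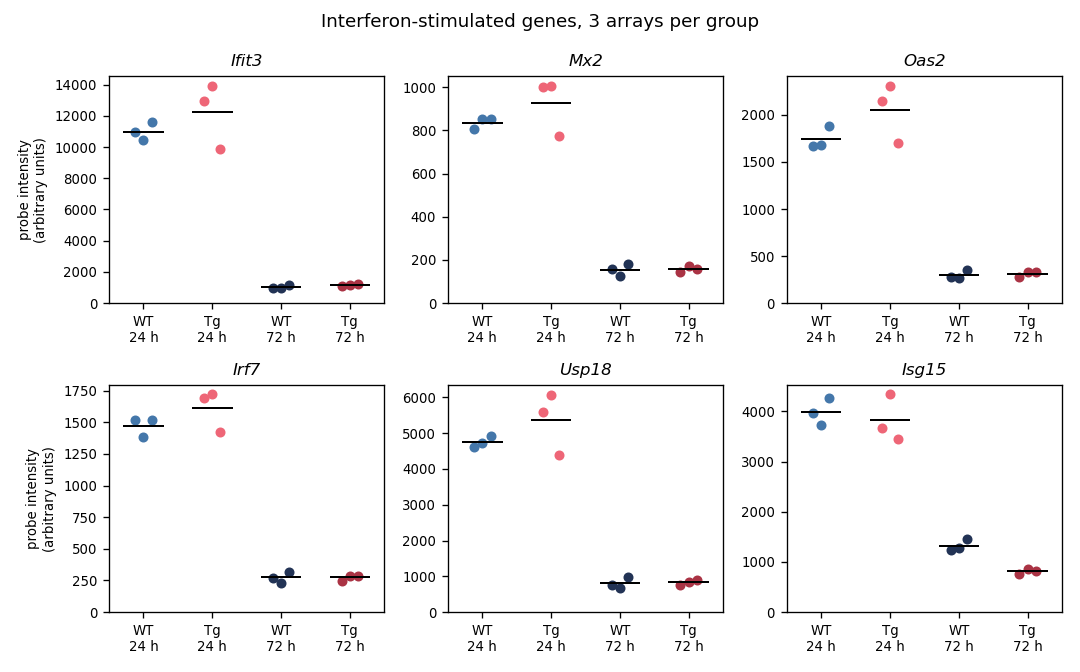
Probe intensity in arbitrary units of 6 interferon-stimulated genes in the 4 groups, with 1 point per array and the group mean as a black line. Ifit3 averaged 10990 in WT and 12250 in Tg at 24 h, against 1043 and 1143 at 72 h.

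In Tg spleens the same interferon genes fell from 24 h to 72 h, and erythroid, neutrophil and some acinar genes rose. All 28 interferon genes fell (28 adjusted over the list alone, mean -1.64, camera adjusted p = 3.53e-44, and 7.02e-06 with an estimated correlation), with Ifit3 at -3.38 (12250 ± 2090 to 1143 ± 64.7, SE 0.0593, adjusted p = 1.07e-11), Mx2 at -2.89, Oas2 at -2.82, Irf7 at -2.69, Usp18 at -2.67 and Isg15 at -2.20. Sct, the gut hormone secretin, fell by 2.62 on the log2 scale (1182 ± 220 to 220.3 ± 24.3). Of 24 erythroid genes 20 rose (also 20 adjusted over the list alone, mean 0.76, camera adjusted p = 3.45e-23, and 6.18e-05 with an estimated correlation), including Hemgn (1.52), Kel (1.22), Ank1 (1.22) and Klf1 (1.10). Of 26 proliferation genes 21 rose (22 adjusted over the list alone, mean 0.42, camera adjusted p = 3.11e-15, and 0.00051 with an estimated correlation), such as Rrm2 (0.88) and Birc5 (0.62).

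Of 30 acinar genes 16 rose, 13 did not pass and 1, the kallikrein Klk1, fell by 0.79 (16 and 1 adjusted over the list alone, camera adjusted p = 3.79e-16, and 0.00051 with an estimated correlation). The list mean was 0.91 and the median 0.42, or 0.30 with 13 genes at their bounds, and the caveat on independent evidence holds here as well. Amy2a5 rose from 106.8 ± 18.2 to 3397 ± 272 (log2 5.87, SE 0.0812, adjusted p = 1.33e-12). Its other probes gave 2.43 and 0.07. Both were undetected at 24 h and the latter also at 72 h, so these are fitted values. The lipase-related Pnliprp1 rose at least 3.47-fold, Zg16 at least 2.81-fold, Cela2a at least 2.80-fold, Clps at least 2.24-fold and Reg1 at least 2.19-fold. The other Clps probe gave 0.43 but was undetected at both times. Dct rose at least 3.36-fold.

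Of 17 neutrophil genes 10 rose (11 rises and 1 fall adjusted over the list alone, mean 0.30, camera adjusted p = 8.94e-06, and 0.0045 with an estimated correlation), among them the granule protein genes Ngp (0.75), Camp (0.69) and lactoferrin (Ltf, 0.65). Of 10 megakaryocyte genes 5 rose (6 adjusted over the list alone, mean 0.23, camera adjusted p = 0.002, and 0.0243 with an estimated correlation), such as the platelet chemokine Ppbp (0.42). Chemokine genes (13 of 24 fell and 1 rose, 14 and 1 adjusted over the list alone, mean -0.46, camera adjusted p = 4.83e-08), macrophage genes (7 of 17 fell, 7 falls and 1 rise adjusted over the list alone, mean -0.22, camera adjusted p = 0.000619) and mature dendritic cell genes (4 of 10 fell, 5 adjusted over the list alone, mean -0.24, camera adjusted p = 0.00117) fell, with Cxcl10 at -1.87, Il1b at -0.81, C1qb at -0.71 and Cd86 at -0.57. Their adjusted p with an estimated correlation was 0.00172, 0.0152 and 0.0211. Monocyte genes (5 of 12 fell and 1 rose, 5 and 2 adjusted over the list alone, mean -0.35, camera adjusted p = 0.00782, adjusted p = 0.0667 with an estimated correlation) and plasmacytoid dendritic cell genes (4 of 8 fell, 4 falls and 1 rise adjusted over the list alone, mean -0.42, camera adjusted p = 0.0142, adjusted p = 0.0615 with an estimated correlation) lost their calls there. The latter group's largest fall was that of Bst2 (-1.91), an interferon-stimulated gene on both lists, and Klk1 is shared with the acinar list. With the mean of each gene's probes its adjusted p was 0.0654 (0.00178 to 0.0654 over all alternatives). The T cell call (4 of 12 rose, also 4 adjusted over the list alone, mean 0.15, camera adjusted p = 0.0482, adjusted p = 0.164 with an estimated correlation) ended without any 1 of WT 24 h replicates 1, 2 and 3, Tg 24 h replicate 2 and Tg 72 h replicate 2 (0.0531 to 0.0917), and also with the replicate block, with median scaling and with detection on all 12 arrays (0.0509 to 0.174).

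Lists that were not called in Tg and whose mean, median and test did not share a sign were those of ribosomal (mean 0.03), oxidative phosphorylation (-0.02), circadian clock (-0.01), housekeeping (0.05), conventional dendritic cell (-0.01), duct (0.00), B cell (0.01), ER stress (0.01) and eosinophil genes (-0.03). In Tg 877 genes rose and 781 fell, of which 32 rose and 74 fell at least 2-fold. With median scaling the split was 725 up and 977 down. Of the fitted changes of at least 2-fold, 12 rises were acinar genes, 7 rises erythroid genes and 18 falls interferon genes. Among the acinar rises, the bounds of Reg2 (1.17-fold), Cpb1 (1.3), Try4 (1.34), Rnase1 (1.38), Try5 (1.53) and Spink1 (1.57) lay under 2-fold. The time comparisons in WT and Tg share no array, but they too come from 1 fit, so their calls are not independent. They had 544 rises (150.7 for independent calls) and 495 falls (110.8) in common and 30 genes in opposite directions (258.6). Across genes the log2 differences correlated at r = 0.6239 and rho = 0.4946.

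**Figure D4:**
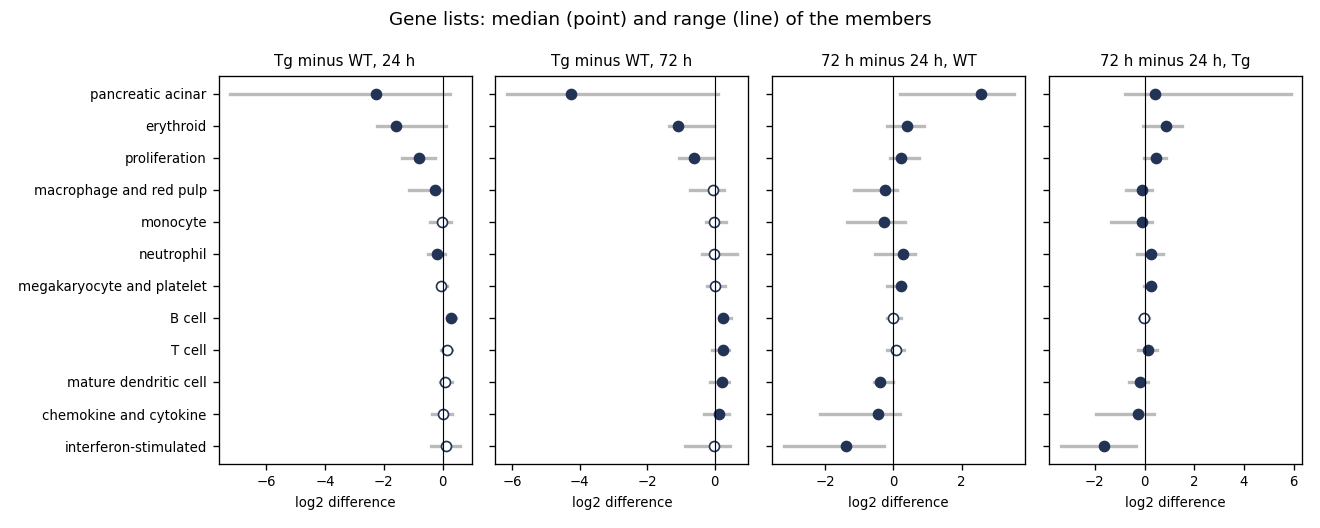
Median log2 difference of the members of each list (point) with the lowest and highest member (grey line) in the genotype comparisons at 24 h and 72 h and the time comparisons in WT and Tg, with x axes that differ between panels. Filled points have a camera adjusted p under 0.05, such as the acinar list at -2.26 at 24 h and -4.27 at 72 h, and open points do not.

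The interaction asked whether the Tg minus WT difference itself changed from 24 h to 72 h. In the acinar list 25 of 30 genes fell in this contrast, 2 rose and 3 did not pass (26 and 2 adjusted over the list alone, mean -1.38, median -1.42, camera adjusted p = 6.28e-38, and 6.79e-05 with an estimated correlation). These are fitted values, since 22 of the 30 genes were undetected in Tg at 24 h, where their deficit has no measured size. Of 7 genes detected on all 12 arrays 5 fell, 1 rose and 1 did not pass (mean -0.58, median -1.15), the falls being those of Ctrl (-2.48), Gp2 (-1.89), Cela1 (-1.41), Klk1 (-1.15) and Erp27. In the whole list Pla2g1b (-3.40, adjusted p = 1.04e-09), Cela3b (-2.90), Pnliprp2 (-2.88), Ctrb1 (-2.76) and Cel (-2.66) led the falls. All 5 were undetected in Tg at both times, and Pla2g1b and Pnliprp2 were detected on WT arrays at 72 h alone, so these values are no folds. Amy2a5 rose by 3.80, and Reg2, undetected in Tg at 24 h, rose as well. The other Amy2a5 probes gave 0.30 and -1.70, which are fitted values, as both were undetected in Tg at 24 h. The erythroid deficit of Tg shrank, with 13 of 24 genes rising and 11 not passing (16 rises and 2 falls adjusted over the list alone, mean 0.39, camera adjusted p = 6.25e-11, and 0.00106 with an estimated correlation), led by Hemgn (1.04, SE 0.0885, adjusted p = 3.34e-05), the carbonic anhydrases Car1 (0.90) and Car2 (0.68), Ank1 (0.81) and Kel (0.64). Dct also passed (adjusted p = 4.94e-10), at least 3.42-fold lower in Tg at 24 h and at least 3.29-fold higher at 72 h, and because it was undetected in Tg at 24 h and in WT at 72 h the size of this change is not given.

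The other interaction calls were lost with an estimated correlation. Of 26 proliferation genes 5 rose and 1 fell (9 and 1 adjusted over the list alone, mean 0.18, camera adjusted p = 0.000568, adjusted p = 0.059 with an estimated correlation), for example Cdc6 (0.82). Of 17 macrophage genes 2 rose (3 rises and 1 fall adjusted over the list alone, mean 0.20, camera adjusted p = 0.0134, adjusted p = 0.0753 with an estimated correlation), and median scaling ended that call (adjusted p = 0.0618, against 0.00605 to 0.0618 over all alternatives). Of 8 plasmacytoid dendritic cell genes 2 fell (also 2 adjusted over the list alone, mean -0.37, or -0.25 without Klk1, camera adjusted p = 0.0185, adjusted p = 0.079 with an estimated correlation), and with the mean of each gene's probes the adjusted p was 0.33 (0.00603 to 0.33 over all alternatives). Of 28 interferon genes 4 fell (2 rises and 9 falls adjusted over the list alone, mean -0.17, camera adjusted p = 0.0222, adjusted p = 0.0762 with an estimated correlation), led by Isg15 (-0.79), and the call ended without Tg 24 h replicate 1 (-0.16, adjusted p = 0.062, against 0.00843 to 0.062 over all alternatives). Of 24 chemokine genes 2 rose (also 2 adjusted over the list alone, mean 0.10, camera adjusted p = 0.0288, adjusted p = 0.0892 with an estimated correlation), with Ccl19 at 0.50, and the call ended without WT 24 h replicate 2, Tg 24 h replicate 1, WT 72 h replicate 2 or Tg 72 h replicate 1 or 2 (0.0521 to 0.0682). The ribosomal (mean 0.01, median -0.01), cytotoxic (-0.03 and 0.02) and B cell (-0.00 and 0.04) lists were not called and had means and medians of opposite sign.

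In all, 237 genes rose and 310 fell in the interaction, 5 and 35 of them with a fitted change of at least 2-fold. Of these 35 falls 22 were acinar genes, and for genes undetected in Tg at 24 h the values are no folds. With median scaling the split was 193 and 476. Leaving out single arrays lowered the count by over 1.5 times without WT 24 h replicate 1 (311), Tg 24 h replicate 2 (330) or 3 (323), WT 72 h replicate 2 (350) or 3 (337), or Tg 72 h replicate 1 (345) or 2 (334).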

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

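The tests of the acinar, erythroid and proliferation patterns were chosen only after the results were seen, and the counts over other splits of the arrays were planned before. The results below stand out because the Tg minus WT difference differed between 24 h and 72 h by limma's interaction test. That held for 547 genes and, by camera, for the acinar list (fitted mean change -1.38, from -2.45 to -3.83), the erythroid list (0.39, from -1.32 to -0.94), the proliferation list (0.18, from -0.78 to -0.61) and the macrophage list (0.20, from -0.27 to -0.08). It also held for the plasmacytoid dendritic cell list (-0.37, from 0.11 to -0.26), the interferon list (-0.17, from 0.10 to -0.07) and the chemokine list (0.10, from 0.01 to 0.11). Without Klk1, which is also on the acinar list, the plasmacytoid list changed by -0.25, from 0.22 to -0.04 (median 0.13). For the acinar list 22 of 30 genes were undetected in Tg at 24 h, so their difference there has no measured size, and of the 7 genes detected on all 12 arrays 5 fell and 1 rose (mean -0.58). Only the acinar and erythroid lists kept their call with an estimated correlation. The single genes below are those the naming rule took. The pancreatic enzymes Pla2g1b (-3.40), Cela3b (-2.90), Pnliprp2 (-2.88), Ctrb1 (-2.76) and Cel (-2.66) fell. These 5 were undetected in Tg at both times, so their values are fitted values and no folds. The amylase Amy2a5 (3.80) and Hemgn (1.04, from -2.22 to -1.18) rose. The other Amy2a5 probes gave 0.30 and -1.70, also fitted values, as both were undetected in Tg at 24 h. Ear6, a ribonuclease of the eosinophil family (1.02, from -0.93 to 0.09, adjusted p = 0.0176), and the complement receptor gene Vsig4 (1.19, from -1.15 to 0.04, adjusted p = 0.0305) were both near the detection limit, and their values are fitted values too. Dct changed its direction (fitted value 5.12), with intensities of 185.8 in WT and 60.5 in Tg at 24 h, and 59.43 and 177.5 at 72 h. It was undetected in Tg at 24 h and in WT at 72 h, so only bounds hold, at least 3.42-fold lower in Tg and then at least 3.29-fold higher.

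With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave the highest count in each comparison of a pair of groups, as 1 of the 10 splits. It called 2248 genes between genotypes at 24 h, 2122 at 72 h, 3156 over time in WT and 1658 over time in Tg, where the highest of the other splits called 0. Every other split mixes the 2 groups, which puts their difference into the spread and lowers the count by construction. For the interaction, 2 of 100 drawn splits of the 12 arrays gave at least as many genes as the real 547. The other of the 2 called 3114 genes. It exchanged whole groups between genotypes at 1 time, and so measured a main effect, a structure of the samples rather than chance. Of 98 splits that mixed groups, 85 called 0 genes and the highest called 357. Mixing groups that differ widens the spread (median residual SD 0.1467 against 0.1042 for the real split) and so lowers these counts by construction, and the share says nothing on chance.

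The acinar transcripts, lower in Tg at both times, are the pattern a reader may most want to follow. With time 28 of 30 genes rose in WT, and 16 rose and 1 fell in Tg. Normalization is argued against, because the list's mean difference was -1.76 at 24 h and -2.99 at 72 h in the intensities as deposited. A pancreatic RNA mix of fixed composition in different amounts stays open. The log2 ratios of WT 72 h to WT 24 h had an SD of 0.829 over 18 genes (0.573 over 17 genes without Reg2). The median SE of 1 ratio was 0.141 (0.138 without Reg2), but it holds only the spread between arrays that may be technical. Probes of 1 gene differed too, as for Clps (3.35 and 2.86 after normalization), and compression of bright probes was not tested. Pancreatic tissue taken along with the spleen stays open, since 29 of 34 acinar genes on the array were detected on all WT 72 h arrays, while 0 of 17 endocrine genes were, which leaves acinar tissue alone open. At 72 h 2 of 7 duct, 2 of 5 adipocyte and 1 of 4 skeletal muscle genes were also lower in Tg and 0 higher, but these lists were not called. A genotype difference stays open too, because time and pool of mice coincide and the list rose by 2.29 in WT and by 0.907 in Tg within 1 genotype.

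The erythroid and proliferation genes, lower in Tg at 24 h and at 72 h, form the other pattern in whole spleen. The next 2 checks cover 24 h alone and use list differences already reported above. More blood with mature red cells in WT spleens at 24 h is argued against as the only source of both differences. It would leave the proliferation list unmoved, but 25 of its 26 genes fell. That list differed by -0.782 (camera adjusted p = 7.01e-05 with an estimated correlation). This difference is itself part of the pattern, so it is no separate test of the erythroid genes. For the erythroid difference alone, more blood in WT stays open. A lower erythroid share alone would raise every other cell type alike, whereas the B cell list rose and the macrophage list fell at 24 h, 0.569 apart. Both directions were known before this check. The 2-sided permutation p over genes (1e-05, the smallest the permutations can give) treats genes as independent and measures no spread between arrays or mice. A genotype difference and a difference between pools of mice could not be separated, as the erythroid list also rose by 0.378 in WT and 0.764 in Tg with time. Cell numbers were not measured, and whether the proliferation genes belong to red cell precursors was not tested.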

How the results depend on the processing

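The added count of all tested probes was chosen after seeing the data, and all other alternatives were planned. Over the alternatives, 101 of 118 counts of genes stayed within 1.5 times and 17 moved. Of 3844 values of lists, 3622 kept their direction and side of the threshold, 159 newly passed it, 62 no longer did and 1 reversed. Of those that newly passed, 48 came from the directional and 87 from the mixed test of fry, which ask another question than camera, and the mixed test has no direction. Of 22020 values of named genes the numbers were 20573, 416, 1025 and 6. The interaction count of 547 became 827 without background correction, 331 without a filter on dim probes, 1034 with trend and robust variances, and 40 at 2-fold or more. The filter result follows in part from the larger number of probes tested, and the cause of the others was not tested. Counting only changes of at least 2-fold left 169 genes between genotypes at 24 h, 115 at 72 h, 115 over time in WT and 106 in Tg, as the rule itself does, and counting probes in place of genes gave 4013 and 3772 between genotypes. With an estimated correlation the interaction of the proliferation list (0.1767, adjusted p = 0.059) and of the interferon list (-0.1715, adjusted p = 0.0762) no longer passed.

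Values that reversed were the ribosomal list in the interaction with median scaling (-0.1627) and, with the mean of a gene's probes, Hprt (-0.05794) and Actb (-0.08936) between genotypes at 24 h, Cd44 (-0.01726) at 72 h, Gusb (-0.1252) and Siglech (-0.04226) over time in WT and Spib (0.206) over time in Tg. For the means, probes of 1 gene that differ are the construction, and for the ribosomal list the cause was not tested. The median log2 difference of all genes lay between -0.0443 and 0.0421 in every comparison with quantile normalization, median scaling or no background correction. The call of 8 follicular helper genes at 72 h also ended under 6 other settings (adjusted p 0.0504 to 0.0829), that of the chemokine genes at 72 h under 2 (0.0504 to 0.0653) and in the interaction under 3 (0.0541 to 0.0914), and that of the mature dendritic cell genes at 72 h with a fit of only the groups compared (0.0529).

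Leaving out 1 array at a time gave 1634 to 2203 genes between genotypes at 24 h, 1547 to 2163 at 72 h, 2489 to 3141 over time in WT, 1167 to 1655 in Tg and 311 to 434 in the interaction. The acinar list stayed between -2.477 and -2.422 at 24 h and between -3.839 and -3.825 at 72 h, and the interferon interaction between -0.1849 and -0.1624. Over all alternatives the acinar list moved more, between -2.491 and -1.572 at 24 h and between -3.856 and -2.231 at 72 h. With the replicate number as a replicate block the counts were 2191, 2052, 3079, 1568 and 444, in the order above. Deviations of arrays with the same number correlated at -0.04367 to 0.1572 (median 0.01052), and those with other numbers at -0.1618 to 0.1706 (median -0.01601). Of 12 arrays 7 were closest to their own number, so whether the numbers pair the arrays stays undecided. The authors' scores, used without gene names, gave 1674 probes between genotypes at 24 h and 3159 at 72 h. The nearest counts are the 4013 and 3772 probes above, but they are not like for like. The scores were fitted on all probes complete at that time, without the detection filter and on the arrays of that time alone. The probe counts above come from the tested probes in the fit of all 12 arrays. The tally at the start set the scores against counts of genes. They were not run for the time comparisons, the interaction, the lists or named genes, because scores of different times and their probe names could not be tied together. Signal over background limits the dim genes, which have only bounds.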

Other observations

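The tests of the probe pattern in the last paragraph were chosen only after the result was seen. Single genes of the ER stress and plasma cell lists moved in both directions. At 24 h the ER disulfide isomerases Pdia3 (0.30, adjusted p = 0.00321) and Pdia4 (0.24) and the co-chaperone Dnajc3 (0.38) were higher in Tg, while Atf4 (-0.33, adjusted p = 0.00472), Sdf2l1 (-0.23, adjusted p = 0.0448) and Ighg1 (-0.40, adjusted p = 0.00574) were lower. At 72 h Pdia4 (0.30), calreticulin (Calr, 0.35), Creld2 (0.41, adjusted p = 0.000215) and Sdf2l1 (0.43) were higher and Atf4 (-0.29) and Ighg1 (-0.88, adjusted p = 1.83e-05) were lower, and for Creld2 (0.38), Sdf2l1 (0.67) and Ighg1 (-0.48) the genotype difference changed between the times. The ER stress list as a whole was not called at 24 h (3 of 15 rose and 1 fell, adjusted p = 0.915) or at 72 h (4 rose and 1 fell, adjusted p = 0.219), nor was the plasma cell list (3 of 10 rose and 2 fell at 24 h, adjusted p = 0.911, and 3 rose and 1 fell at 72 h, adjusted p = 0.191). The conventional dendritic cell list was not called at 72 h (adjusted p = 0.0547), and of its single genes H2-DMb2, which helps load peptides, stood at 0.54 (adjusted p = 0.00369), the chain H2-Ab1 at 0.34 and the invariant chain Cd74 at 0.33.

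Other genes moved alone. Ier3, a stress response gene, was higher in Tg at 24 h (0.45, adjusted p = 0.000649) and lower at 72 h (-0.50, adjusted p = 0.000337), and its interaction was -0.95. In WT the killer cell genes Prf1, or perforin (0.58), and Klra8 (0.50) rose with time while Fasl (-0.36) and Klrk1 (-0.44) fell, and the cytotoxic list as a whole was not called (mean -0.04, adjusted p = 0.784). The smooth muscle actin Acta2 rose with time in WT (0.57) and in Tg (0.44). Secretin (Sct) had mean intensities of 842.3 in WT and 1182 in Tg at 24 h, and 209.6 and 220.3 at 72 h, and it fell with time in WT (-2.03, adjusted p = 2.39e-09) and in Tg (-2.62). A search made after the values were seen found 27 genes with fitted values at least 2-fold lower in Tg at both times and at least 2-fold higher at 72 h in WT. Of these, 21 were on the acinar list, 1 on another (Tff2), and 5 on none, namely Gm10334, Gm5409, Gm5771, the pancreatic disulfide isomerase Pdia2 and Tlcd4. Where a gene was undetected in Tg its bound can be smaller, as for Tff2 at 24 h (at least 1.43-fold lower).

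In WT from 24 h to 72 h, 123 of 739 genes with several called probes (16.6%) had probes called in opposite directions, against 5 of 352 in Tg (1.42%), and 64 to 83 genes when single arrays were left out. Actb is an example, with probes at 0.47, 0.11, -0.29, 0.47 and 0.13. Normalization is argued against by at least 107 such genes under other settings (at most 9 in Tg), and although the intensities as deposited gave 4 of 442, the difference between a gene's 2 brightest probes, where array brightness drops out, changed in 602 of 3839 genes in WT and 94 in Tg (431 and 26 after normalization). Probes of cDNA clone records moving against RefSeq probes are argued against as the whole cause, because 70 of the 123 genes had called probes of 1 kind of record, with a median clone minus RefSeq difference of 0.141 in WT, 0.0249 in Tg, 0.103 between genotypes at 24 h and 0.000451 at 72 h. That 1 WT group stands apart from the other 3 stays open. The genotype comparisons had at most 18 such genes, but in the 123 genes the median gap between probes called up and down was 0.297 between genotypes at 24 h and -0.216 at 72 h, against 0.653 in WT and 0.119 in Tg over time. No biological explanation was tested, so the pattern may mark genes whose probes read different transcripts or RNA ends, which stays a hypothesis.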
